A study of Mus musculus with 4 samples.

How the data were processed

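Gene expression was measured by RNA-seq in 4 libraries of OT-I CD8+ T cells, 2 control and 2 exposed to NaBu, grouped by the sample titles. Total RNA was isolated with a column kit for small samples, per the labels' protocols; the library kit and strandedness are not given in the sources used here. Reads were aligned with Bowtie2 and quantified with RSEM against mm10, per the submitters' processing notes; versions are not given in the sources used here. Genes are listed with RefSeq transcript identifiers, per the file headers, and the annotation release is not given in the sources used here. RSEM divides reads that match several genes between them by an estimation step, so values of near-identical genes are less certain than those of other genes.

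The deposited files give, per gene and library, an expected count, an FPKM value and a transcript length, per the file headers. The authors' expected counts are not normalized and need not be whole numbers, and they were rounded to whole numbers before testing. The authors' FPKM values are fragment numbers scaled to transcript length and to the total of mapped fragments, per the file headers, and were used as deposited for the levels in the text. The deposited table of the whole series holds the same FPKM values as the sample files, with a largest difference of 0.0. Together the files list 17559 genes by Entrez identifier, of which 17518 were found in the RefSeq gene table of GRCm38.p6, the assembly also called mm10, from which coordinates were taken. A gene that a library's file does not list was set to 0, the value the series table gives. Mitochondrially encoded genes were not analysed here.

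Expected counts summed to between 19857701 and 20548571 per library. The tested genes held 99.95% of them. Counting intervals are exact binomial 95% intervals on the share of counts, and a group at 0 was set against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

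Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.968, 0.9658, 1.035 and 1.0335 for control 1, control 2, NaBu 1 and NaBu 2), filterByExpr at its defaults, which kept 12943 genes, and the quasi-likelihood F test of NaBu against control with no covariates. P-values were adjusted by Benjamini-Hochberg and called at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. With 2 libraries per group an exact permutation of single values cannot go below a two-sided p of 0.333, so none was run. The model had 2 residual degrees of freedom per gene and a prior of 8.25. On simulated counts of 12722 genes built from this comparison, 78.8% of 66 genes changed 1.5-fold, 85.1% of 67 changed 2-fold and 98.5% of 65 changed 4-fold were called, with 16 of 12524 unchanged genes also called. The simulation changed far fewer genes than were called in the real data and held no GC trend, so these rates need not carry over. With a simulated replicate block, 0 changed genes were called by the fit without a block and 173 by the fit with it.

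A total of 43 gene lists was fixed before the data were examined. Camera of limma 3.58.1, with its preset inter-gene correlation of 0.01, was run on log2 CPM with a prior count of 2 for the 40 lists with at least 5 tested members, and adjusted over those lists. Members past the gene test were counted over all genes tested, and again adjusted over the list alone. The count differed between these only for oxidative phosphorylation, cyclin-dependent kinase inhibitors and G1 cyclins, the unfolded protein response, lysosome and autophagy, and cytosolic ribosomal proteins, where both are given. With an estimated correlation, which rests on 2 residual degrees of freedom, none of the 40 lists passed.

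The text names genes by a rule fixed at the same time. It takes the 10 largest changes per direction among called genes with a mean FPKM of 5 or more in the higher group and no overlap between the groups, leaving out predicted genes. It adds up to 4 called members per list, by size of change, with an FPKM of 1 or more, and 15 genes chosen by name, giving 184 genes. Other genes in the text were chosen after their values were seen. These were *Stat4*, *Il18r1*, *Il18rap*, *Lta*, *Tgfb1*, *Gzma*, *Nkg7*, *Fasl*, *Batf*, *Mki67*, *Ung*, *Myc*, *Jun*, *Nefh*, *Nfatc2*, *Gapdh*, *Cd4* and *Eef1a1* in the report, and the family and marker genes of the closing section that fall outside the rule. Some genes that the rule takes are not reported here.

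The alternatives were median-of-ratios factors, library totals, no filter on low counts, a minimum of 5 CPM in at least 2 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with an FPKM of 1 or more in at least 2 libraries, limma on log2(FPKM + 1) without that filter, limma-voom, DESeq2 1.42.0, edgeR's glmTreat against a fold change of 1.5, the replicate number as a block, and leaving out each library. A fit without 1 library has 1 residual degree of freedom, and assumes that the lone library of its group varies like the 2 of the other group. For the lists, fry and the estimated correlation were added. Removal of each library's trend on transcript GC content, by a lowess fit with a span of 0.3, was added after the data were seen, for the 12397 tested genes (95.8%) with a GC value in GENCODE M21. Tables were handled with Python 3.11.15 and pandas 2.3.3, and intervals with scipy 1.17.1.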

Results

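RNA-seq was performed on mouse CD8+ T cells of the C57BL/6 strain, taken from tissue labelled LN, that carry the OT-I transgene, a T cell receptor recognising a peptide of ovalbumin. The cells had been purified by negative magnetic selection to above 95% and stimulated with plate-bound anti-CD3 (1 µg/ml) and anti-CD28 (2 µg/ml) in IL-2 (10 ng/ml) for 2 d, followed by 2 d in IL-2 without the antibodies. They were then left untreated or exposed to 1 mM NaBu for 12 h. NaBu is the usual abbreviation of sodium butyrate, a short-chain fatty acid salt known as an inhibitor of histone deacetylases. There were 2 control and 2 NaBu libraries. Expected counts assigned to genes summed to 20344399 in control 1, 20548571 in control 2, 19859649 in NaBu 1 and 19857701 in NaBu 2. Genes with an FPKM of 1 or more numbered 10722 and 10627 in the controls and 11220 and 11250 in the NaBu libraries. The most abundant transcript by counts was *Eef1a1* in the controls, with 1.52% and 1.51% of counts, and *Gzmb*, encoding granzyme B, in the NaBu libraries, with 1.36% and 1.35%. Within each group the libraries differed by more than counting noise, with a chi-square per degree of freedom of 7.65 for the controls and 2.83 for NaBu. Nothing in the labels says whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

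The comparison of NaBu with control asked how exposure to butyrate changed the transcriptome of activated CD8+ T cells, including effector genes and the receptor and regulators of IL-12 signalling. Cytokine and chemokine genes, effector regulators, immediate early genes and lysosomal genes were higher after NaBu, and genes of mitosis, DNA replication, sterol and fatty acid synthesis and ribosome biogenesis were lower, by camera with its preset correlation. None of these list calls held with an estimated correlation (adjusted p from 0.633 to 0.645). That test rests on 2 residual degrees of freedom and passed none of the 40 lists, not even those with a negative estimate. It could therefore not decide for or against single lists. With fry, which does not compare a list with other genes, all 15 lists past camera passed. The changes covered most of the expressed genome. Of 12943 tested genes, 8884 (68.6%) passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, of which 4471 were higher and 4413 lower in NaBu. A change of 2-fold or more was seen for 2984 of them, 1934 higher and 1050 lower. The first principal component held 93.3% of the variance, and the common biological coefficient of variation was 0.0524. Against a fold change of 1.5 as the null, 3779 genes passed, 2214 higher and 1565 lower. With library totals alone as the scale, the median log2 fold change of all tested genes moved from 0.005 to 0.102, so all directions given here are relative to the TMM scale.

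**Figure D1:**
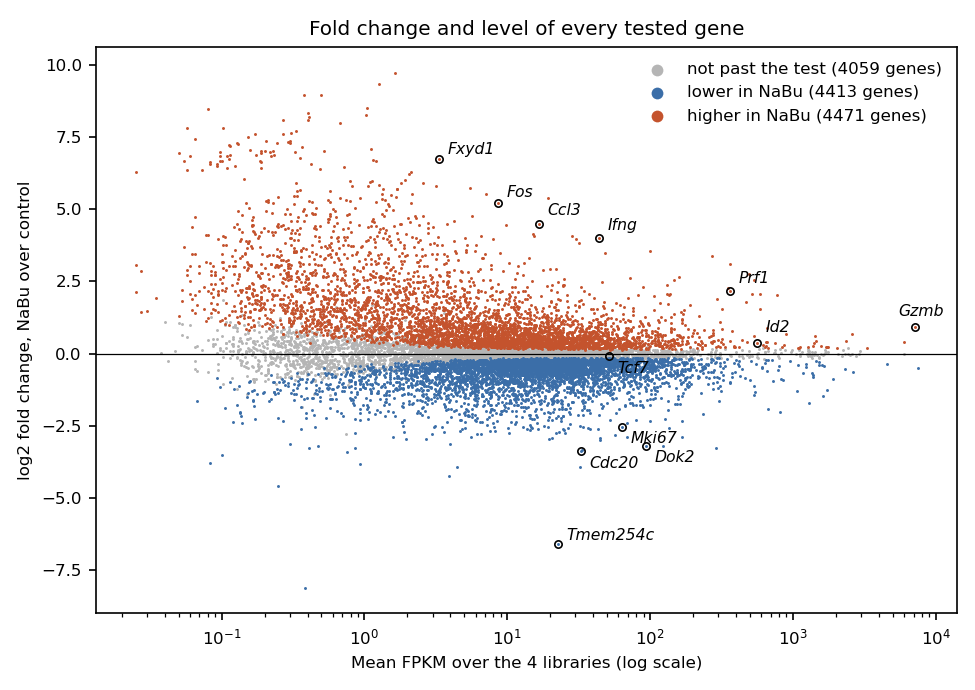
Log2 fold change of NaBu over control against the mean FPKM over the 4 libraries (log scale), with 1 point per tested gene, coloured by the edgeR call. The 4471 higher genes extend to large fold changes at low levels, where fitted values of genes with few or no control counts depend on the prior count, and 12 genes are circled and named.

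The genes of IL-12 and type 1 signalling, through which interleukin-12 drives interferon gamma production, moved in both directions, with 8 of 15 tested members higher and 4 lower. *Il12rb1* (gene 16161, mm10 chromosome 8, 70808360 to 70823542) and *Il12rb2* (gene 16162, chromosome 6, 67285986 to 67376293), which encode both chains of the IL-12 receptor, rose 1.68-fold and 1.85-fold. *Il12rb1* had an FPKM of 105.9 and 94.5 in the controls and 180.1 and 179.8 in the NaBu libraries. *Il12rb2* went from an FPKM of 94.2 ± 0.933 to 185.0 ± 6.36 (SD, n = 2 per group, as for all such values here). *Id2* (gene 15902, chromosome 12, 25093799 to 25096092), an inhibitor of E-protein transcription factors, rose 1.29-fold, from 468.0 ± 4.47 to 647.0 ± 4.79, with a log2 fold change of 0.37 ± 0.06 (SE) and an edgeR adjusted p of 0.000308. That change was below the fold of 1.5 used as a stricter null (adjusted p = 1.0 with edgeR's glmTreat). *Tbx21*, the gene of the type 1 regulator T-bet, rose 2.16-fold, *Hlx* 4.31-fold and *Ifngr2*, a chain of the interferon gamma receptor, 2.92-fold. *Il27ra* fell 3.2-fold, and the genes of the IL-18 receptor, *Il18r1* and *Il18rap*, fell 1.77-fold and 1.57-fold. *Stat4*, which transmits the IL-12 signal, had an FPKM of 59.6 in controls and 60.6 in NaBu and did not pass the test (adjusted p = 0.378 by edgeR). As a set the list did not pass camera (adjusted p = 0.307).

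Of the effector cytokines and chemokines, 11 of 17 tested genes rose and 2 fell, with a median log2 fold change of 1.11. *Ifng* (gene 15978, chromosome 10, 118441046 to 118445894), encoding interferon gamma, went from an FPKM of 4.83 ± 0.368 to 83.2 ± 6.56, a log2 fold change of 4.01 ± 0.1 (SE) with an edgeR adjusted p of 1.29e-09. The chemokine genes *Ccl3* and *Ccl4* rose 22.8-fold and 14.4-fold. *Il10*, encoding an immunoregulatory cytokine, rose 15.8-fold from an FPKM of 3.39 ± 1.23 to 57.2 ± 1.13. *Tnf* rose 4.06-fold, from 30.9 ± 6.43 to 134.0 ± 12.1. *Lta*, encoding lymphotoxin alpha, rose 10.5-fold, whereas *Ltb*, encoding its partner lymphotoxin beta, fell 3.36-fold and *Tgfb1* also fell, with a log2 fold change of -0.54. The list was higher by camera (adjusted p = 0.00279), and adjusted p = 0.633 with an estimated correlation. Of 7 tested myeloid and dendritic cell markers (of 19 listed), 6 were also higher, and *Xcr1* was lower. *Itgam* rose 8.93-fold to an FPKM of 4.31 ± 0.735 and *Mpeg1* 6.03-fold to 1.91 ± 0.0707.

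The cytotoxic effector genes split, with 11 of 24 higher, 8 lower and 5 not past the test (camera adjusted p = 0.789). *Gzmb* (gene 14939, chromosome 14, 56258836 to 56262334) rose from an FPKM of 4742 ± 45.6 to 9630.0 ± 66.8, a 1.9-fold change. *Prf1* (gene 18646, chromosome 10, 61297751 to 61304684), encoding the pore-forming protein perforin, rose 4.51-fold, from 124.0 ± 21.0 to 600.0 ± 18.5. *Gzma* rose 1.59-fold, with a log2 fold change of 0.67 ± 0.07 (SE). Lower members included *Unc13d*, needed for granule release, which fell 3.0-fold, and *Ctsw*, encoding cathepsin W, which fell 1.96-fold. *Nkg7*, encoding a granule membrane protein, fell 1.91-fold. *Gzmd* fell 2.37-fold, but it lies in a cluster of near-identical granzyme genes between which the counting could have moved reads. *Fasl* did not pass, with an FPKM of 34.6 in controls and 37.7 in NaBu.

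**Figure D2:**
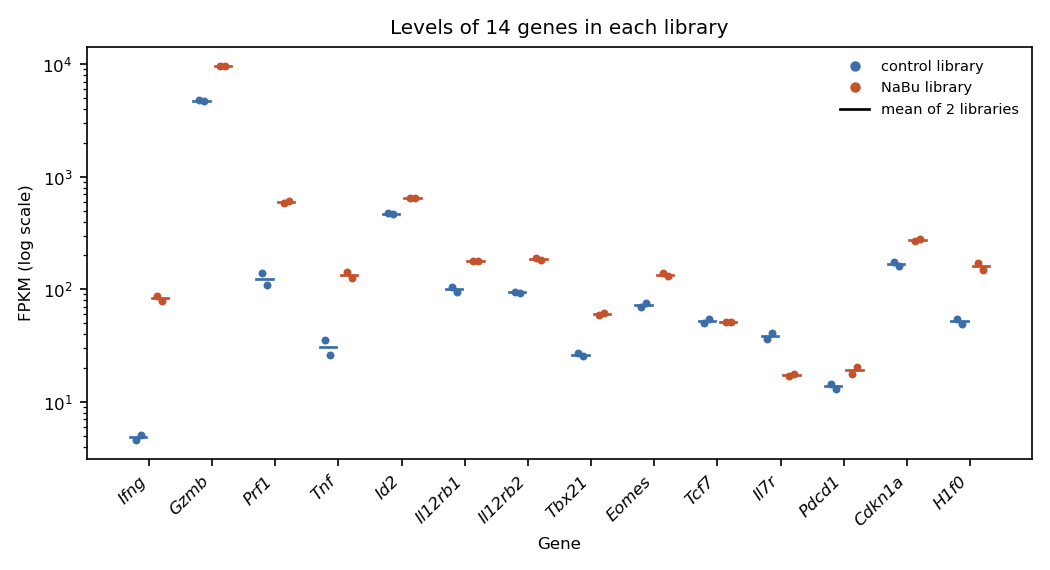
FPKM (log scale) of 14 genes chosen before the data were examined, with 1 point per library and a bar at the mean of the 2 libraries of a group. Both NaBu libraries lay above both controls for *Ifng* (means 83.2 against 4.83) and *Prf1* (600.0 against 124.0), below both for *Il7r* (17.2 against 38.2), and overlapped the controls for *Tcf7*.

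Effector differentiation factors were higher as a group, with 11 of 14 tested genes higher and 2 lower (camera adjusted p = 0.0108, and adjusted p = 0.633 with an estimated correlation). *Prdm1*, encoding Blimp-1, rose 3.07-fold and *Irf4*, a factor downstream of the T cell receptor, 3.46-fold. *Cx3cr1* rose 5.15-fold but stayed at a low level, with an FPKM of 1.32 ± 0.0778 in NaBu. *Klrg1*, a marker of terminal effectors, fell 3.45-fold but was low in both groups, with an FPKM of 2.1 ± 0.0424 in controls. *Batf* fell with a log2 fold change of -0.51. Naive and memory genes moved both ways, with 7 of 24 higher and 9 lower, and their median of -0.12, mean of 0.01 and camera direction did not share a sign (camera adjusted p = 0.46). *Klf2*, which controls lymphocyte trafficking, rose 5.17-fold and *Ccr7*, a lymph node homing receptor, 2.96-fold. *Il7r*, encoding the IL-7 receptor alpha chain, fell 2.38-fold and *Cd27* 3.19-fold. *Tcf7* did not pass, with a log2 fold change of -0.1 ± 0.06 (SE). Without control 1 it was called lower, with an edgeR adjusted p of 0.0237, in a fit where the remaining control is assumed to vary like the NaBu libraries. *Eomes* rose 1.72-fold.

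Among inhibitory receptors and exhaustion genes, 10 of 18 rose and 5 fell, with a median log2 fold change of 0.4 (camera adjusted p = 0.264). *Tox2* had 0 counts in the controls and 167 in NaBu. On library totals this makes it at least 57.3-fold higher against a floor of 3 counts over the group. *Nr4a1* rose 6.48-fold. *Cd160* fell 5.52-fold and *Cd244* 3.26-fold. *Pdcd1*, encoding PD-1, rose 1.29-fold, from an FPKM of 13.8 ± 0.955 to 19.1 ± 1.84, and no longer passed without NaBu 2 (edgeR adjusted p = 0.103). Of 13 costimulatory receptors, 3 rose and 6 fell (camera adjusted p = 0.427), or 4 and 4 on library totals, with *Tnfrsf4*, encoding OX40, 3.68-fold higher and *Slamf1* 3.35-fold higher. Of 19 migration and adhesion genes, 6 rose and 9 fell, with a median of 0.06 against a mean of -0.33 (camera adjusted p = 0.46), or 9 and 9 on library totals. *Gpr183*, an oxysterol receptor that guides lymphocytes, fell 7.4-fold and *Ly6c2* 3.3-fold. *Itgae*, the integrin CD103, fell 5.22-fold from a low level, an FPKM of 3.03 ± 0.255 in controls.

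Genes of cell division fell together. Each of the 32 tested genes of the mitosis list was lower, with a median log2 fold change of -2.29 (camera adjusted p = 2.49e-14, and adjusted p = 0.633 with an estimated correlation). *Cdc20*, an activator of the anaphase-promoting complex, went from an FPKM of 59.1 ± 1.07 to 6.06 ± 0.573, and *Plk1*, a mitotic kinase, from 78.8 ± 1.42 to 10.5 ± 0.608. *Kif20a*, a kinesin of cytokinesis, fell 10.2-fold and *Nuf2*, a kinetochore component, 7.7-fold. *Mki67*, the proliferation marker Ki-67, fell 5.82-fold. Of 32 tested DNA replication genes 31 were lower, with a median of -1.27 (camera adjusted p = 1.12e-10, and adjusted p = 0.633 with an estimated correlation). *Tk1*, encoding thymidine kinase, fell 7.12-fold, *Rrm2*, a ribonucleotide reductase subunit, 4.85-fold and *Cdc45* 3.7-fold. *Ung* was the member that did not pass, with a log2 fold change of 0.05. Cyclin-dependent kinase inhibitors and G1 cyclins were divided, with 6 of 15 higher and 6 lower (7 lower adjusted over the list alone), and their median and mean differed in sign (camera adjusted p = 0.778). *Cdkn1a*, encoding the inhibitor p21, rose 1.51-fold, from 168.0 ± 8.42 to 272.0 ± 7.73, which did not exceed the 1.5-fold null (glmTreat adjusted p = 0.546). *Ccnd1* rose 5.47-fold from a low level, while *Cdkn2c* fell 4.05-fold and *Cdkn1b*, encoding p27, 1.9-fold. Of 16 p53 targets, 4 rose and 9 fell (camera adjusted p = 0.264). The largest fall was that of *Gtse1*, a gene of the G2 and S phases, at 6.68-fold.

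**Figure D3:**
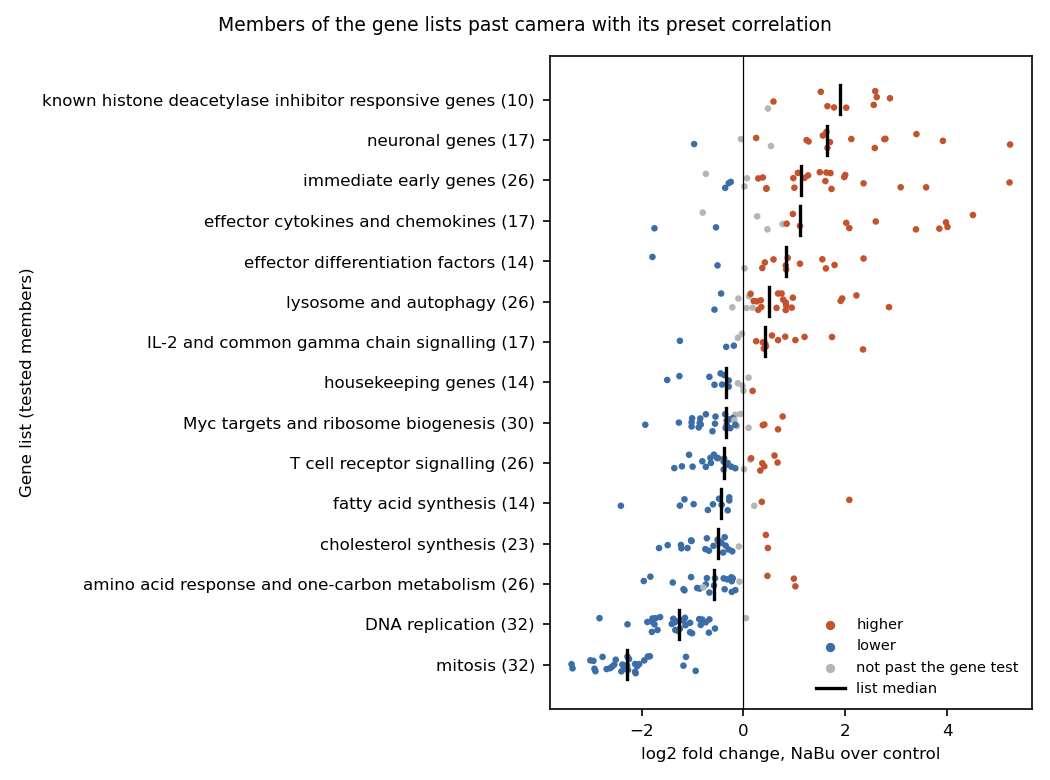
Log2 fold change of NaBu over control for every tested member of the 15 gene lists that passed camera with its preset correlation, with 1 point per gene coloured by the edgeR call and a black bar at the list median. The medians run from -2.29 for mitosis to 1.9 for known histone deacetylase inhibitor responsive genes, and none of the lists passed with an estimated correlation.

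Of 23 cholesterol synthesis genes, 20 fell and 2 rose, with a median log2 fold change of -0.51 (camera adjusted p = 0.000204, and adjusted p = 0.633 with an estimated correlation). *Insig1*, a sterol-regulated gene, fell 3.16-fold and *Idi1*, an isomerase of the isoprenoid pathway, 2.8-fold. Of 14 fatty acid synthesis genes, 11 fell and 2 rose (camera adjusted p = 0.0248, and adjusted p = 0.633 with an estimated correlation). *Fads2*, a fatty acid desaturase, fell 5.33-fold and *Fasn*, encoding fatty acid synthase, 2.37-fold, while *Acacb* rose 4.22-fold to an FPKM of 1.05 ± 0.0707. Of 26 genes of the amino acid response and one-carbon metabolism, 21 fell and 3 rose (camera adjusted p = 0.000724, and adjusted p = 0.645 with an estimated correlation). *Mthfd1l* fell 3.89-fold, *Shmt2*, encoding the mitochondrial serine hydroxymethyltransferase, 2.62-fold and *Psat1*, a serine synthesis enzyme, 2.24-fold. Of 30 Myc targets and ribosome biogenesis genes, 21 fell and 4 rose (camera adjusted p = 0.00279, and adjusted p = 0.645 with an estimated correlation). *Utp20* fell 3.82-fold and *Dkc1*, encoding dyskerin, 2.41-fold, whereas *Myc* itself rose with a log2 fold change of 0.77 ± 0.07 (SE).

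Energy metabolism lists did not pass camera, and on library totals 11 glycolysis genes were higher and 6 lower, and 11 fatty acid oxidation genes higher and 6 lower. Of 21 glycolysis genes, 6 rose and 6 fell (adjusted p = 0.874), with the glucose transporter gene *Slc2a3* 2.45-fold and the hexokinase gene *Hk2* 2.17-fold higher, and *Pfkl* 2.23-fold and *Tpi1* 2.16-fold lower. Of 21 tricarboxylic acid cycle genes, 7 rose and 10 fell (camera adjusted p = 0.46), or 8 and 8 on library totals, and *Pcx*, encoding pyruvate carboxylase, rose 2.33-fold. Of 46 oxidative phosphorylation genes, 13 rose (14 adjusted over the list alone) and 22 fell (camera adjusted p = 0.264), or 16 and 17 on library totals, with *Ndufs8*, a complex I subunit, 2.09-fold lower. Of 24 fatty acid oxidation and ketone use genes, 8 rose and 9 fell, with a median of -0.05 against a mean of 0.04 (camera adjusted p = 0.977). *Etfb*, encoding an electron transfer flavoprotein subunit, rose 1.94-fold and *Acss1*, which makes acetyl-CoA from acetate, fell 1.84-fold. The short-chain fatty acid receptor and transporter list had 3 tested genes, too few for camera, of which *Bsg*, the chaperone of monocarboxylate transporters, rose 1.73-fold. On library totals 2 of them were higher, and with the GC trend removed 2 were higher and 1 lower.

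Genes known to respond to histone deacetylase inhibitors were higher, with 9 of 10 tested genes up, none down and a median log2 fold change of 1.9 (camera adjusted p = 0.000568, and adjusted p = 0.633 with an estimated correlation). *H1f0*, a linker histone gene, rose 2.87-fold, from an FPKM of 52.0 ± 3.67 to 160.0 ± 14.2. *Gsn*, encoding the actin-severing protein gelsolin, rose 6.15-fold and *Mt2*, a metallothionein gene, 5.9-fold. *Hist1h1c*, encoding another linker histone, rose 6.02-fold. Histone genes share near-identical sequence between which reads could be moved. The summed CPM of the 5 tested linker histone genes (of 7 listed) in the lower NaBu library were 2.89 times those of the higher control. Most of that sum came from *H1f0* (14642 counts in NaBu, against 1202 for *Hist1h1c*), so it cannot decide for *Hist1h1c*. None of the 5 genes fell, which argues against reads moved from them. Of 26 genes of histone deacetylases and acetyltransferases, 6 rose and 10 fell (camera adjusted p = 0.457), or 9 and 9 on library totals. *Hdac11* rose 5.2-fold from a low level and *Hdac1* rose 2.25-fold, from 98.7 ± 0.969 to 237.0 ± 11.9. *Sirt1*, encoding an NAD-dependent deacetylase, fell 2.51-fold and *Kat2b*, an acetyltransferase gene, 2.57-fold.

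Immediate early genes were higher in 20 of 26 cases and lower in 3, or 5 with the GC trend removed (camera adjusted p = 0.000369, and adjusted p = 0.645 with an estimated correlation). *Fos* went from an FPKM of 0.42 ± 0.0 to 16.8 ± 3.85, *Egr2* rose 12.0-fold and *Egr1* 8.51-fold, and *Dusp2*, a phosphatase gene of the MAP kinase pathway, 4.0-fold. *Jun* fell, with a log2 fold change of -0.36. Of 26 lysosome and autophagy genes, 19 rose and 2 fell (3 adjusted over the list alone), with a median of 0.5 (camera adjusted p = 0.0021, and adjusted p = 0.645 with an estimated correlation). *Ctsl*, encoding cathepsin L, rose 7.24-fold, *Wipi1* 4.67-fold, *Ctsz* 3.83-fold and the autophagosome gene *Map1lc3a* 3.75-fold. Of 7 tested myeloid and dendritic cell markers (of 19 listed), 6 were also higher and 1 lower. The higher ones included *Cd68*, itself a lysosomal membrane protein gene. Neuronal genes, which T cells express little of, were higher in 14 of 17 tested cases (of 30 listed) and lower in 1. Their median log2 fold change was 1.65 (camera adjusted p = 0.000204, and adjusted p = 0.633 with an estimated correlation). Low-level genes also rose in general. The 3236 tested genes with the lowest mean level had a median of 0.52, and 77.4% of those called were higher. Camera compared the list with all other tested genes. Whether it rose more than genes of similar level was not tested. The kinesin genes *Kif5c* and *Kif5a* rose 15.1-fold and 10.6-fold, the latter to an FPKM of 6.93 ± 0.481, and the synaptophysin gene *Syp* 6.84-fold. *Nefh* fell, with a log2 fold change of -0.97.

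T cell receptor signalling genes were lower in 18 of 26 cases and higher in 6 (camera adjusted p = 0.0351, and adjusted p = 0.645 with an estimated correlation). *Ptprc*, encoding CD45, fell 2.57-fold, *Cd247*, the zeta chain of the receptor complex, 2.32-fold, *Dgka* 2.09-fold and *Ubash3a* 2.01-fold. Higher members included *Nfatc2*, with a log2 fold change of 0.67. The list no longer passed with a minimum of 5 CPM (camera adjusted p = 0.0902) or on log2 FPKM values (0.0562 with a pseudocount of 1 and 0.0611 with 0.1). Of 17 IL-2 and common gamma chain signalling genes, 12 rose and 3 fell (camera adjusted p = 0.0372, and adjusted p = 0.633 with an estimated correlation). The feedback regulator genes *Socs3* and *Socs1* rose 5.11-fold and 2.3-fold, and *Osm*, encoding oncostatin M, 3.33-fold. This list no longer passed without control 2 (camera adjusted p = 0.101), without NaBu 2 (0.0565) or after removal of the GC trend (0.0527). Housekeeping genes, often used as references, were lower in 9 of 14 cases and higher in 1 (camera adjusted p = 0.0383, and adjusted p = 0.633 with an estimated correlation). *Ppia* fell 2.4-fold and *Gusb* 2.83-fold, while *Gapdh* had a log2 fold change of -0.02 ± 0.09 (SE). The housekeeping call was lost on library totals (camera adjusted p = 0.0567), with a minimum of 5 CPM (0.0977), on log2 FPKM values (0.0927 with a pseudocount of 1 and 0.0997 with 0.1) and without NaBu 2 (0.0565). The cytosolic ribosomal proteins had 6 of 40 genes higher and 5 lower, or 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.921). The counts were 12 higher and 1 lower on library totals, and 7 higher and 10 lower with the GC trend removed.

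The 10 largest increases among genes with an FPKM of 5 or more in NaBu were those of *Fxyd1*, *Dact3*, *Pvrl2*, *Atp1b2*, *Mmp9*, *Fxyd7*, *Fos*, *Ypel4*, *Sept4* and *Mcam*. *Fxyd1* and *Fxyd7*, which lie side by side on chromosome 7 and encode regulators of the sodium pump, and *Atp1b2*, encoding a beta subunit of that pump, were all in this group. *Fxyd1* had 1 count in the controls and 140 in NaBu. On library totals this was a ratio of 144, with a 95% exact counting interval of 25.5 to 5730. The edgeR fold on the TMM scale was 108.0. *Atp1b2* went from an FPKM of 0.19 ± 0.0141 to 10.8 ± 0.368. *Mmp9*, encoding a secreted gelatinase, rose 46.1-fold, from 0.28 ± 0.0141 to 14.0 ± 0.283. The 10 largest decreases were those of *Tmem254c*, *Fam64a*, *Khdc1c*, *Cdc20*, *Kif20a*, *Hist1h2ap*, *Hist1h2ao*, *Dok2*, *Plk1* and *Nuf2*. *Dok2*, an adaptor that restrains receptor signalling, fell 9.12-fold, from 167.0 ± 10.2 to 19.6 ± 1.02. *Tmem254c*, *Khdc1c*, *Hist1h2ap* and *Hist1h2ao* have near-identical copies between which the counting could have moved reads, so their values are uncertain. *Khdc1c* did not pass with DESeq2 (adjusted p = 0.16).

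Markers of other cell types moved in both directions. Many listed markers were absent from the files or too low in both groups to be tested, so the counts cover the tested ones only. Of 12 B cell markers 4 were tested, too few for camera, with 3 higher and 1 lower. *Bank1* rose 5.26-fold to an FPKM of 1.25 ± 0.212 and *Cd79b*, part of the B cell receptor, fell 2.32-fold to 2.16 ± 0.389. Of 8 NK cell markers, none rose and 4 fell, or 1 and 3 with the GC trend removed (camera adjusted p = 0.322), including *Klrb1c*, which fell 2.0-fold. Of 19 myeloid and dendritic cell markers 14 were in the files and 7 were tested, of which 6 rose and 1 fell (camera adjusted p = 0.0896). *Itgam*, encoding the integrin CD11b, rose 8.93-fold to an FPKM of 4.31 ± 0.735 and *Cd68* rose 2.48-fold, while *Xcr1* fell 2.72-fold. Of 13 stromal and endothelial markers 5 were tested, of which 3 rose and 1 fell (camera adjusted p = 0.372). *Pdgfrb* was 16.4-fold higher at an FPKM of 1.35 ± 0.219. Of 2 erythroid and platelet markers tested, *Hba-a1* rose 7.1-fold to an FPKM of 6.92 ± 0.46, a value its near-identical copy leaves uncertain. Of 8 CD4 and regulatory T cell markers, 3 rose and 1 fell (camera adjusted p = 0.46), and *Cd4* reached an FPKM of 0.655 in NaBu. Of 5 germline genes, 1 rose and 1 fell (camera adjusted p = 0.944), *Brdt* by 5.13-fold upwards and *Piwil2* by 2.04-fold downwards.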

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

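The GC correction was chosen after the data were seen, and the other alternatives before. The count of changed genes, 8884, lay between 7399 (DESeq2) and 9164 (GC trend removed) under other tools, scalings and filters, and between 7099 and 8850 when 1 library was left out, with the lowest value without NaBu 2. The spread in those fits comes from the 2 libraries of the other group, and the lone library is assumed to vary like them. Leaving out a library gave 3617 to 4418 genes higher and 3479 to 4432 lower, and 13 to 15 gene lists. Genes called in the opposite direction numbered 3 with the GC correction, 1 without control 2 and 0 under the other alternatives. Against a 1.5-fold null, 3779 genes passed, 2214 higher and 1565 lower, since that test asks for a larger change. The count at 2-fold or more, 2984, fell to 1824 with a minimum of 5 CPM, which tests fewer low-level genes, to 1531 with limma on log2(FPKM + 1) and to 1523 on that scale without a filter. It was 2104 with limma on log2(FPKM + 0.1), so the pseudocount accounts for part of the fall, and the cause of the rest was not tested. It ranged from 2836 to 3080 when 1 library was left out. On library totals the split was 5175 higher and 3720 lower (58.2% against 50.3% higher on the TMM scale). The 15 gene lists past camera became 0 with an estimated correlation and 29 with fry, which does not compare a list with other genes, and were 13 to 15 otherwise. Lists lost elsewhere were T cell receptor signalling, IL-2 signalling and housekeeping genes, and the cause was not tested. Of the 184 named genes, *Zbtb7b* changed sign, from a log2 fold change of 0.29 to -0.02 with the GC correction (adjusted p = 0.667). Depth limits the fold of genes with few control counts, as for *Fxyd1*, whose counting interval runs from 25.5 to 5730.

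Control and NaBu libraries share the numbers 1 and 2, but the labels do not say that these pair the samples. The deviations of same-numbered libraries from their group means correlated at -0.09 across 10087 genes, and genes are not independent replicates. With the replicate block, 8853 genes were called, 4468 higher and 4385 lower, 2991 of them at 2-fold or more, and 14 lists, the IL-2 list being the one that no longer passed (adjusted p = 0.0591).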

Other observations

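The GC correction and the tests of the ratio of library sizes, of other cell types and of summed family CPM were chosen after the data were seen, as were the values for the X chromosome and for genes near 0 in one group. Interferon-stimulated genes did not move as one group, with 11 of 33 higher and 13 lower, or 13 higher and 11 lower on library totals (camera adjusted p = 0.921, and median and mean of opposite sign). The guanylate-binding and immunity-related GTPases, which act against intracellular pathogens, rose in 17 of 18 tested cases, with *Gbp2* 6.81-fold, *Gbp10* 6.33-fold and *Igtp* 2.91-fold higher. *Gbp3* was the exception, with a log2 fold change of 0.08 ± 0.1 (SE). In the Oas, Ifit and Mx families, typical of the response to type I interferon, 1 of 15 genes rose and 8 fell, or 3 and 7 on library totals. *Oasl1* fell 2.92-fold and *Ifit3* 2.1-fold. All 10 tested genes of the MHC class II group rose on the TMM, median-of-ratios and library-total scales, most from low levels. The highest, *H2-Ab1*, went from an FPKM of 27.3 ± 4.89 to 61.5 ± 0.276. In NaBu *H2-Oa* had a mean FPKM of 31.2, *H2-DMa* 26.7, *Cd74* 6.61 and *H2-Aa* 1.29. Cells of the B, myeloid and dendritic types also express these genes, and markers of those types moved in both directions. Among 7 tested myeloid and dendritic markers (of 19 listed) 6 were higher, with *Itgam* 8.93-fold and *Mpeg1* 6.03-fold up, and *Xcr1* fell 2.72-fold. The B cell marker *Bank1* was 5.26-fold higher, whereas *Cd79b* fell 2.32-fold. Antigen presentation genes as listed had 8 of 18 higher and 6 lower, or 10 and 3 on library totals (camera adjusted p = 0.612), and the immunoproteasome gene *Psmb10* fell 2.95-fold.

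Stress and death genes were divided. Of 25 apoptosis genes, 11 rose and 9 fell, or 8 and 10 with the GC trend removed (camera adjusted p = 0.977), with the pro-apoptotic genes *Bmf* and *Bcl2l11*, encoding BIM, 9.44-fold and 2.94-fold higher and the caspase inhibitor gene *Xiap* 2.26-fold lower. Of 21 unfolded protein response genes, 8 rose and 8 fell (9 adjusted over the list alone), or 9 and 5 on library totals (camera adjusted p = 0.982), the sensors *Atf6* and *Ern1* by 2.93-fold and 2.36-fold upwards and the chaperone gene *Hsp90b1* by 1.57-fold downwards. Of 11 heat shock genes, 4 rose and 6 fell (camera adjusted p = 0.821). *Hspb1* rose from an FPKM of 0.28 and 0.0 in the controls, with 5 counts in all, to 3.72 and 3.16 in NaBu, with 122 counts. Of 22 metallothionein and oxidative stress genes, 11 rose and 6 fell (camera adjusted p = 0.427), with *Mt1* 4.05-fold and *Hmox1*, encoding heme oxygenase, 2.36-fold higher. The median, mean and test differed in sign for the apoptosis, unfolded protein response, heat shock and germline lists. The 414 tested genes of the X chromosome had a median log2 fold change of -0.23 against 0.01 for 12501 autosomal genes. After the GC correction the medians were -0.14 and 0.02.

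Genes at low levels rose more often than others. Among the 3236 genes with the lowest mean level, 1487 of 1922 called genes (77.4%) were higher in NaBu, against 36.9% of the called genes among the 3236 with the highest level. An FPKM of 1 or more in both NaBu libraries with less than 0.2 in both controls was seen for 121 genes, and the reverse for 9. Deeper NaBu libraries are argued against by the ratio of mean totals, NaBu over control, of 0.971, and a GC trend as the whole cause by the 78.2% of called low-level genes that still rose after the GC correction. RNA from other cell types could not be excluded. The median log2 fold change of 10 tested abundant markers of B, NK, myeloid, erythroid and stromal cells was 0.29. Of these, 4 were higher (*Ctss*, *Aif1*, *Apoe* and *Hba-a1*) and 2 lower (*Cd79b* and *Klrb1c*). The other 4 (*Fcer1g*, *Tyrobp*, *Lst1* and *Col1a2*) did not pass the test. A median over several cell types cannot decide for any single type, and the purification to above 95% leaves room for a few such cells. An opening of silent genes by histone deacetylase inhibition remains a hypothesis that was not tested separately from the treatment.

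Fold changes also rose with transcript GC content. The 10% of genes with the highest GC content exceeded the 10% with the lowest by 0.54 in log2 fold change (Spearman's rho 0.18 across genes, which are not independent replicates). The same difference was -0.29 between the control libraries (rho -0.47) and 0.07 between the NaBu libraries (rho 0.15). The larger within-group difference was thus 0.54 of that between groups, which is consistent with GC bias between libraries adding to small fold changes. An effect of the treatment on genes of high GC content stays open beside it.

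The rise of the GTPases may be a response to the cells' own interferon gamma, whose transcript rose 16.1-fold. A separate list of genes induced by interferon gamma, written before its values were seen, had 9 tested genes (of 14 listed). Of the tested ones 7 (77.8%) rose, whereas 34.5% of all tested genes rose. The 7 included *Irf8*, which rose 5.24-fold, *Irf1*, 2.85-fold, and *Cd274*, encoding PD-L1, 3.59-fold. The exceptions were *Cxcl10*, which fell 3.33-fold, and *Lgals3bp*, which fell 1.63-fold. Reads moved between near-identical family members are argued against, as the summed CPM of the family in the lower NaBu library were 3.19 times those of the higher control. A GC trend is argued against too, since 16 of the 17 members called higher (94.1%) stayed so after the GC correction, and the other, *Iigp1b*, had no GC value and was not tested there. A direct effect of NaBu on these genes remains open, since no library separates it from secreted interferon gamma.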
